A study of Mus musculus with 8 samples.

How the data were processed

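Messenger RNA was sequenced from mouse inducible regulatory T cells (iTregs), which are naive CD4 T cells turned into Foxp3-expressing cells in culture. Per the labels' protocols, naive CD4 T cells from spleen and lymph nodes of Foxp3-eGFP mice were activated through CD3 and CD28, differentiated with or without CPI-1205, an inhibitor of the histone H3 lysine methyltransferase EZH2, and sorted on GFP. The labels assign 4 libraries to untreated iTregs and 4 to iTregs differentiated with CPI-1205, each with a letter from A to D. The dose, the length of exposure and the number of cultures or mice were not given in the sources used here.

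Per the labels' protocols, RNA was prepared on silica columns with DNase digestion and made into directional poly(A) libraries. Per the submitters' processing notes, TopHat2 2.1.0 and HTSeq were used with the mm10 genome build. The deposited table holds raw counts of reads per Entrez gene for the 8 libraries, without normalization by the authors. The annotation release, the strand setting and the counting mode were not given in the sources used here. Reads from overlapping or antisense genes, and reads shared by near-identical copies, could therefore have been dropped or given to either gene, and the affected families are named as uncertain.

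The table lists 27179 Entrez gene identifiers, of which 25275 (93%) were found in the RefSeq gene table for GRCm38.p6, the assembly that mm10 denotes. That table gave all coordinates, which count from 1. In 27 rows the gene name had been turned into a date, and the name was restored from the identifier. A further 847 rows carry an identifier without a name. They hold 0.0379% to 0.0441% of the counts of a library and stayed in the library sizes and tests under their identifiers. Mitochondrial genes are named without a prefix, as in the deposited table.

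Total counts per library ranged from 16592109 to 34047598. Genes were kept with edgeR's filterByExpr by group, which left 12550 genes. Library sizes were scaled with TMM factors, which were 0.934 to 0.944 in untreated and 1.04 to 1.08 in treated libraries. CPM are the usual counts-per-million values on the TMM-scaled library size, and means of CPM are given with the SD over the libraries of a group. Differences between groups were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are treated over untreated, log2 CPM for the set tests used a prior count of 2, and standard errors are the absolute log2 fold change divided by the square root of the F statistic. For a gene with 1 to 3 counts over the untreated libraries, the ratio of counts is given with its 95% counting interval, and for a gene with 0 counts a lower bound against a floor of 3 counts over the group. These intervals and bounds cover counting error only, since the reads carry no molecular identifiers.

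The test, the filter, the 26 gene lists, the rule for named genes and the alternatives listed first below were fixed before the data were examined. Lists with at least 5 measured members, 24 of them, were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 24 lists. The lists covered PRC2, PRC1 with H3K27 demethylases, developmental Polycomb targets, the Treg signature, Th1 and cytotoxic, Th2, Th17, Tfh, naive and homing genes, inhibitory receptors, costimulatory and TNF receptors, chemokines with their receptors, cell cycle, CDK inhibitors and p53 targets, interferon response, TGF-beta response, cholesterol synthesis, glycolysis and hypoxia, immediate early and stress genes, B cell, myeloid, CD8 and NK, erythroid and stromal markers, sex-linked genes and mitochondrially encoded genes. A single list symbol, Hbb-bt, was not found in the table. The rule named Ezh2, Eed, Suz12, Ezh1 and Foxp3 always. It also named the 12 genes that rose most and the 12 that fell most among genes past the threshold, with an average log2 CPM of at least 1 and no overlap of the groups, passing over gene models without a conventional symbol, of which there was 1 among the lowered genes. Last, it named up to 4 members of each list with the smallest adjusted p. Genes named beyond this rule were chosen after their values were seen, and are marked as such.

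Alternatives comprised DESeq2-type, upper-quartile and no composition factors, no filter and a filter of 1 CPM in 4 libraries, the letter as a block, each library left out in turn, DESeq2 1.42.0, limma voom, an adjusted p threshold of 0.01, a 2-fold minimum, edgeR's test against a 1.2-fold change, camera with an estimated correlation and fry. Alternatives added after seeing the data were a coefficient of variation fixed at 0.1 or 0.2, thinning of every library to the smallest total, and leaving out both treated libraries with the largest share of ribosomal precursor counts.

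The procedure was tested on simulated data, with genes changed by known folds. Counts were drawn from a negative binomial model with the means, library sizes and estimated spread of these 8 libraries. Of 12406 simulated genes, the test recovered 32% of those changed 1.1-fold, 64% at 1.2-fold, 89.8% at 1.5-fold and 97.9% at 2-fold, and called 4 of 12210 unchanged genes. A simulated shifted list was called, and 0 of 20 unchanged lists were, with genes drawn independently of one another. The simulation changed few genes, 50, 50, 49 and 47 of those tested at these folds, whereas most genes tested in the data passed. These rates therefore need not hold for the data. They also take the spread between these libraries, which may be technical, as the true spread.

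Replicates were compared before averaging. A chi-square test of the counts of each pair of libraries within a group gave a mean of 1.44 to 5.39 per gene and a median of 1.17 to 1.43 relative to chance, above the value of 1 that sampling noise gives, so no libraries were merged and all 8 were kept. Separate preparations of the same RNA would also exceed sampling noise, so this does not show that the libraries are independent.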

Results

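The transcriptomes of iTregs differentiated without (untreated) or with the EZH2 inhibitor CPI-1205 (treated) were compared, with 4 libraries in each group. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3. The untreated libraries A to D held 29969868, 28810034, 16592109 and 32099723 counts, and the treated libraries A to D held 19483255, 34047598, 33117692 and 25757995. The groups separated along the first principal component, which held 92% of the variance against 2.19% for the second. Pearson correlations of log2 CPM across genes were 0.9946 to 0.9971 within groups and 0.9322 to 0.9363 between groups.

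Of 30 Th1 and cytotoxic genes 24 rose in treated iTregs, and of 23 measured chemokines and chemokine receptors 16 rose. Limma's camera called both lists higher (adjusted p = 1.49e-05 and 0.0103), but neither with an estimated correlation between genes (adjusted p = 0.0631 and 0.0703). Perforin (Prf1), the pore-forming protein of killer cells, rose from 9.42 ± 0.21 to 580 ± 9.2 CPM (SD, n = 4), and granzyme B (Gzmb) from 181 ± 4.0 to 1589 ± 25 CPM. Of 23 glycolysis and hypoxia genes 21 fell, and of 30 cell cycle genes 29 fell (adjusted p = 0.0399 and 0.0126 with an estimated correlation), among them the glucose transporter Slc2a1, from 258 ± 1.1 to 100 ± 0.75 CPM, and the proliferation marker Mki67, from 66.4 ± 0.85 to 21.7 ± 0.75 CPM. Foxp3, which encodes the lineage transcription factor of Tregs, fell 1.58-fold in cells that had been sorted on a Foxp3 reporter. Of the 12550 genes tested, 2170 (17.3%) changed at least 2-fold, 1581 upward and 589 downward, and with library size as the only scaling 1918 upward and 377 downward.

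Foxp3 (Entrez 20371, chromosome X, 7579676 to 7595243 of GRCm38) was at 114 ± 1.4 CPM in untreated and 72.0 ± 2.0 CPM in treated cells (SD, n = 4), a log2 fold change of -0.66 with a standard error of 0.022. Ezh2 itself (Entrez 14056, chromosome 6, 47530274 to 47595270) went from 152 ± 1.4 to 102.3 ± 1.2 CPM, a log2 fold change of -0.57 with a standard error of 0.018. The adjusted p in edgeR was 1.54e-26 for Foxp3 and 2.35e-27 for Ezh2. With a coefficient of variation fixed at 0.2, edgeR's likelihood ratio test gave adjusted p of 0.00481 for Foxp3 and 0.0174 for Ezh2. Suz12, a PRC2 core subunit, fell by 0.80 on the log2 scale. Eed, the core subunit that binds methylated H3K27, gave -0.16, but with library size as the only scaling its value was 0.02, past no threshold. Nor did Eed pass with the coefficient of variation fixed at 0.1 (adjusted p = 0.169, likelihood ratio test). Ezh1, the alternative catalytic subunit, stood at 35.4 ± 0.56 and 36.6 ± 1.2 CPM and did not pass the threshold (adjusted p = 0.231 in edgeR), although it passed with upper-quartile factors and with library size only. In the GENCODE annotation, genes on the opposite strand overlap Foxp3, Ezh2, Eed and Suz12, and a gene on the same strand also overlaps Foxp3 and Eed, so all 4 values are uncertain if counting ignored strand, and those of Foxp3 and Eed in either case.

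Across all 12 measured PRC2 components, 8 fell, 1 rose (Phf1, named after its value was seen) and 3 did not pass, with a median log2 fold change of -0.49, and with library size only 7 fell and 3 rose. The smallest adjusted p were those of Suz12, Rbbp7 (-0.69) and Aebp2 (-0.63). Jarid2 (-1.14), named after its value was seen, fell most and was the only member past 2-fold. The list was called lower by camera (adjusted p = 0.0301), a call lost at adjusted p = 0.124 with an estimated correlation. Of 20 measured PRC1 members and H3K27 demethylases, 5 rose, 12 fell and 3 did not pass, with a median of -0.29, and with library size only 8 rose and 10 fell, with a median of -0.11. Bmi1, a PRC1 subunit, rose 2.19-fold, whereas Pcgf5 (-1.12) and the demethylase gene Kdm6b (-1.34) fell. That list was not called (adjusted p = 0.089). Only 8 of 55 developmental Polycomb targets had enough counts to be tested, of which 6 rose and 2 fell (camera adjusted p = 0.171, and 0.0414 without a count filter). Hoxb4 went from 2.57 ± 0.13 to 6.25 ± 0.26 CPM and Igf2 from 0.195 ± 0.086 to 1.18 ± 0.39 CPM (SD, n = 4), and Foxc1 and Bmp7 also rose. For each of the 26 lists, the number of members called when adjusted over the list alone equalled the number called over all genes tested.

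Granzymes made up much of the top of the list of raised genes. Gzma (Entrez 14938, chromosome 13, 113093824 to 113100981) had 2 counts over the 4 untreated libraries and 31936 over the treated ones, reaching 267 ± 4.1 CPM (SD, n = 4), a ratio of 13430 with a 95% counting interval of 3718 to 110900. Gzme had 0 counts in untreated cells and was at least 1180-fold higher in treated cells. Gzmd had 1 untreated count, for a ratio of 4192 (752 to 165600). Gzmc rose 272-fold from 0.572 ± 0.15 to 150 ± 2.9 CPM. Gzmc, Gzmd and Gzme lie within the granzyme cluster of chromosome 14, between 56117619 and 56241647, and resemble one another in sequence, so the split of reads among them is uncertain. Ly6g, a member of the Ly6 family of related surface proteins and uncertain for the same reason, had 1 untreated count and a ratio of 1792 (321 to 70800). The hyaluronan receptor Layn and the guanine deaminase Gda, each with 3 untreated counts, had ratios of 202 (68.7 to 980) and 165 (56.2 to 803). The chemokine Ccl9 rose 195-fold, the chemokine receptor Ccr5 (chromosome 9, 124121543 to 124127183) 128-fold, the cytokine Il21 116-fold, the interferon-induced membrane protein gene Ifitm1 112-fold and Baalc 109-fold.

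Among the 12 genes that fell most, Prm2, which encodes a sperm protamine, fell from 5.64 ± 0.33 to 0.132 ± 0.10 CPM (SD, n = 4), a log2 fold change of -5.35. On the log2 scale, the zinc transporter Slc39a2 (-4.02), the keratin Krt81 (-3.80), the GTPase Rhoj (-3.67) and Mreg (-3.59) followed. Ccr6 (Entrez 12458, chromosome 17, 8236041 to 8258519), the receptor for Ccl20, fell from 42.8 ± 1.3 to 3.21 ± 0.23 CPM. Pla2g4f (-3.54), Avpr1a (-3.54), the osteoprotegerin gene Tnfrsf11b (-3.50), Lad1 (-3.38), Muc13 (-3.26) and the muscle enolase gene Eno3 (-3.16) completed the 12. Among the genes of largest change, antisense genes overlap Il21, Baalc, Avpr1a and Muc13, and Btg4 and Mettl17 overlap Layn and Slc39a2, which leaves their counts uncertain. Adjusted p in edgeR over these 12 lowered genes ran from 4.86e-39 for Lad1 to 1.27e-24 for Prm2.

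**Figure D1:**
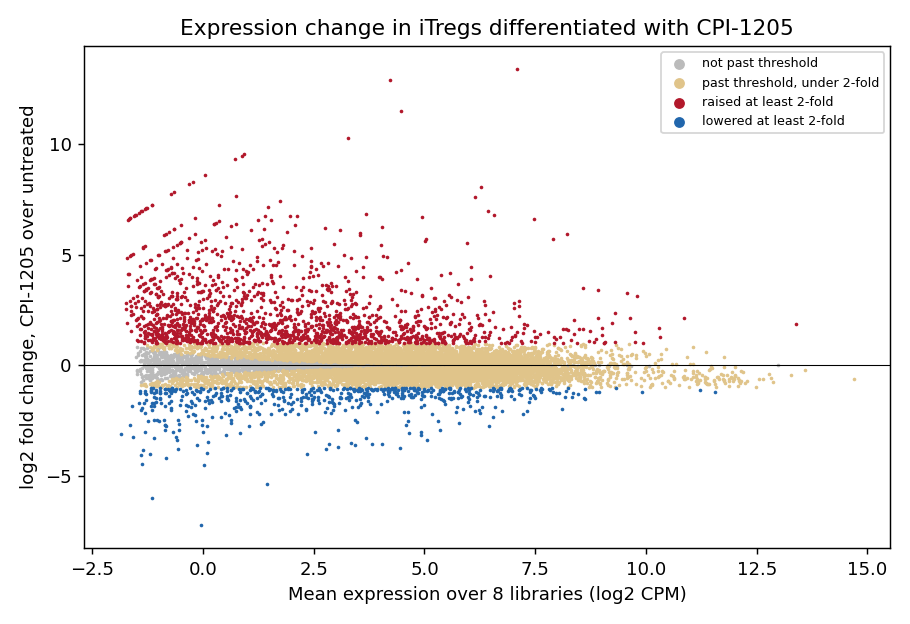
Each point is 1 of the 12550 tested genes, with mean expression over the 8 libraries (log2 CPM) on the horizontal axis and the log2 fold change of CPI-1205 over untreated iTregs on the vertical axis. Red and blue points are the 1581 raised and 589 lowered genes past the threshold at 2-fold, tan points passed at smaller folds and grey points did not pass. Fitted folds of genes with 3 or fewer counts in a group depend on the prior count.

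Members of the Treg signature moved in both directions. Of 35 measured members, 20 rose, 13 fell and 2 did not pass, and the list as a whole was not called by camera (adjusted p = 0.168). Among the raised genes were Fgl2, a secreted suppressive molecule, which rose 52.7-fold from 8.81 ± 0.51 to 465 ± 7.5 CPM (SD, n = 4), Ecm1 (7.57-fold) and the inhibitory receptor Lag3 (3.70-fold). Genes chosen after their values were seen include Il10, an anti-inflammatory cytokine (1.81 ± 0.26 to 44.8 ± 0.84 CPM), Prdm1, the gene for the transcription factor Blimp-1 (4.89 on the log2 scale), and Il2ra, the high-affinity IL-2 receptor chain (1690 ± 11 to 2181 ± 36 CPM). Also chosen after their values were seen were Treg-associated genes that fell with Foxp3. The transcription factor Ikzf2 (Helios) went from 74.9 ± 1.8 to 9.71 ± 0.73 CPM, Ikzf4 (Eos) from 37.5 ± 1.8 to 22.9 ± 0.66 CPM, Nrp1 from 141 ± 3.2 to 69.0 ± 1.4 CPM and Ccr8 from 270 ± 4.5 to 124 ± 2.4 CPM.

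**Figure D2:**
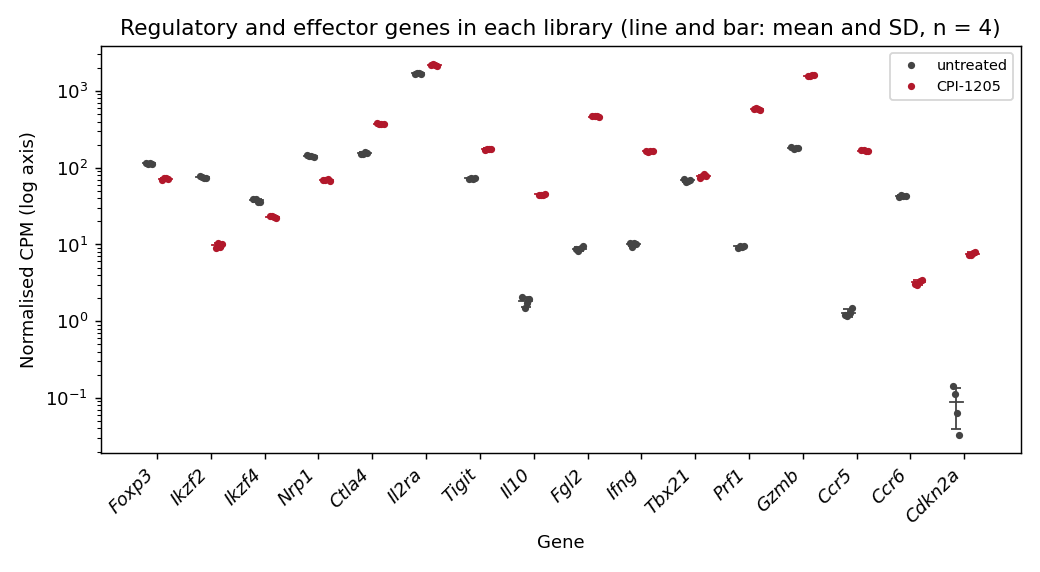
Normalised CPM on a log axis for 16 genes, chosen after their values were seen, in the 4 untreated (grey) and 4 treated (red) libraries, with the mean as a line and the SD as a bar. Foxp3, Ikzf2, Ikzf4, Nrp1 and Ccr6 lie lower in every treated library, and Il10, Fgl2, Ifng, Prf1, Gzmb, Ccr5 and Cdkn2a lie higher.

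Of the 30 Th1 and cytotoxic genes, 24 rose and 6 fell, with 18 of them raised at least 2-fold and a median log2 fold change of 1.63. The list was called higher (camera adjusted p = 1.49e-05), and the adjusted p was 0.0631 with an estimated correlation. Besides Prf1, Gzma, Ccr5 and Gzmb, and chosen after their values were seen, the effector cytokine Ifng went from 10.1 ± 0.54 to 164 ± 3.4 CPM (SD, n = 4), and the receptor subunit Il12rb2 from 12.9 ± 0.52 to 110 ± 3.8 CPM. Of the transcription factor genes in the list, also chosen after their values were seen, Tbx21, which encodes T-bet, went from 68.4 ± 2.6 to 78.0 ± 3.3 CPM, Eomes from 30.4 ± 0.88 to 18.8 ± 0.78 CPM and Hlx from 0.0952 ± 0.080 to 4.99 ± 0.31 CPM, while Stat4 rose 1.78-fold, and Runx3 and Bhlhe40 rose by 0.23 and 0.20 on the log2 scale. Among 17 inhibitory receptors and ligands, 11 rose and 6 fell, without a call for the list (camera adjusted p = 0.089). Havcr2, which encodes the exhaustion marker TIM-3, rose 21.6-fold, Ctla4 2.44-fold and Tigit 2.41-fold.

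Chemokines and their receptors moved in the same direction as the cytotoxic genes, with 6 genes shared by the lists. Of 23 measured, 16 rose, 6 fell and 1 did not pass, with a median log2 fold change of 2.07 (camera adjusted p = 0.0103, and adjusted p = 0.0703 with an estimated correlation). The lymphotactin gene Xcl1 went from 82.8 ± 2.3 to 881 ± 24 CPM and Ccl1 from 32.3 ± 1.6 to 243 ± 4.8 CPM (SD, n = 4), beside the rises of Ccl9 and Ccr5. Ccr6 and Ccr8 were the 2 members that fell at least 2-fold.

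Genes of other helper lineages also changed. In the Th2 list 12 of 16 rose and 4 fell (camera adjusted p = 0.0301, adjusted p = 0.23 with an estimated correlation, and 0.12 with library size only), including Il24 (6.37-fold), Maf (2.45-fold) and Il4ra (1.07 on the log2 scale), while the phosphatase gene Dusp4 fell. Chosen after its value was seen, Gata3, the Th2 lineage factor, fell by 0.79 on the log2 scale. In the Th17 list 10 of 16 rose and 6 fell, without a call (adjusted p = 0.282). The ion channel genes Tmem176a and Tmem176b, which overlap in the genome and share reads to an unknown extent, rose 59.1-fold and 29.8-fold beside Il21, whereas Ccr6 and, chosen after its value was seen, Rorc (-1.31) fell. In the Tfh list 7 of 16 rose, 7 fell and 2 did not pass (adjusted p = 0.857), with a median of -0.03 and a mean of 0.19. Pdcd1 rose 1.59-fold, and Tcf7 (-1.33) and Btla (-1.74) fell. Of 20 naive and homing genes 8 rose, 10 fell and 2 did not pass (adjusted p = 0.616). The integrin Itgb7 and the chromatin organiser Satb1 rose 2.44-fold and 2.56-fold, and Tcf7 and Foxp1 (-0.83) fell. The medians of these last 2 lists turned positive with library size as the only scaling (0.16 with 8 raised and 5 lowered, and 0.11 with 9 raised and 9 lowered). Of 20 costimulatory and TNF receptor genes 8 rose, 11 fell and 1 did not pass (adjusted p = 0.471), with a median of -0.22 and a mean of 0.02, and with library size only 9 rose and 9 fell. Tnfrsf9 (4-1BB) rose 2.48-fold and Tnfsf10 (TRAIL) 1.71-fold, while Tnfrsf1b (-0.72) and Tnfrsf4 (-0.52) fell.

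Of 30 cell cycle genes, 29 fell and 1 (Gins2, named after its value was seen) rose, with a median of -0.52, and 3 fell at least 2-fold, and with library size only 23 fell and 1 rose. Camera called the list lower (adjusted p = 7.64e-08), and the call held with an estimated correlation (adjusted p = 0.0126). Beside Mki67 (-1.61), the mitotic kinesin Kif11 fell 1.97-fold, the mitotic kinase Aurkb 1.90-fold and cyclin A2 (Ccna2) 1.80-fold. Of 22 CDK inhibitors and p53 targets, 13 rose, 7 fell and 2 did not pass (adjusted p = 0.171), with a median of 0.10, and with library size only 17 rose and 3 fell, with a median of 0.29. Cdkn2a, the locus of the cell cycle inhibitors p16 and p19, rose from 0.0877 ± 0.048 to 7.58 ± 0.33 CPM (SD, n = 4), a sum over its overlapping transcripts. The pro-apoptotic gene Bcl2l11 rose 3.35-fold, Gadd45g 3.43-fold and Pmaip1 1.55-fold.

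Interferon response genes rose. Of 32 measured members, 27 rose, 4 fell and 1 did not pass, with a median of 0.65 and 14 raised at least 2-fold. Camera called the list higher (adjusted p = 6.92e-05, and adjusted p = 0.0288 with an estimated correlation). Ly6a, which encodes Sca-1, went from 141 ± 3.7 to 1374 ± 24 CPM (SD, n = 4), the guanylate-binding protein genes Gbp2 and Gbp7 rose 3.21-fold and 4.76-fold, and the nucleic acid sensor Zbp1 rose 2.15-fold. Ly6a and the guanylate-binding proteins belong to families of related copies.

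Glycolysis and hypoxia genes fell. Of 23, 21 fell, 7 of them at least 2-fold, and 2 rose, with a median of -0.83 (camera adjusted p = 5e-07, and adjusted p = 0.0399 with an estimated correlation). Ero1l fell from 588 ± 3.5 to 208 ± 1.8 CPM (SD, n = 4), the oxygen sensor Egln3 from 425 ± 5.9 to 156 ± 1.5 CPM and the lactate exporter Slc16a3 from 469 ± 6.0 to 174 ± 2.1 CPM, beside Slc2a1. The 2 members that rose were Aldoc (0.11) and Hif1a, the gene for the hypoxia-inducible factor, which went from 259 ± 1.8 to 504 ± 8.9 CPM. Both were named after their values were seen. In the cholesterol synthesis list 15 of 21 genes fell, 4 rose and 2 did not pass, all under 2-fold, with a median of -0.22 (camera adjusted p = 0.0301, adjusted p = 0.124 with an estimated correlation, and 0.179 with library size only, where 10 fell and 7 rose). Examples are Cyp51 (-0.38), Fdft1 (-0.47), Srebf2 (-0.34) and Sqle (-0.36).

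Among 27 immediate early and stress genes, 9 rose, 16 fell and 2 did not pass (camera adjusted p = 0.0917), and with library size only 10 rose and 13 fell. Nr4a1, an early target of T cell receptor signalling, fell from 262 ± 3.1 to 63.2 ± 1.9 CPM (SD, n = 4), and Nr4a3 (-1.50), Myc (-1.03) and Ier2 (-0.86) also fell. Of 25 TGF-beta response genes 14 rose, 10 fell and 1 did not pass (adjusted p = 0.303). Serpine2 rose 4.74-fold, Id2 3.32-fold and the integrin Itgae (CD103) 2.20-fold, and the receptor gene Tgfbr1 fell 1.99-fold.

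**Figure D3:**
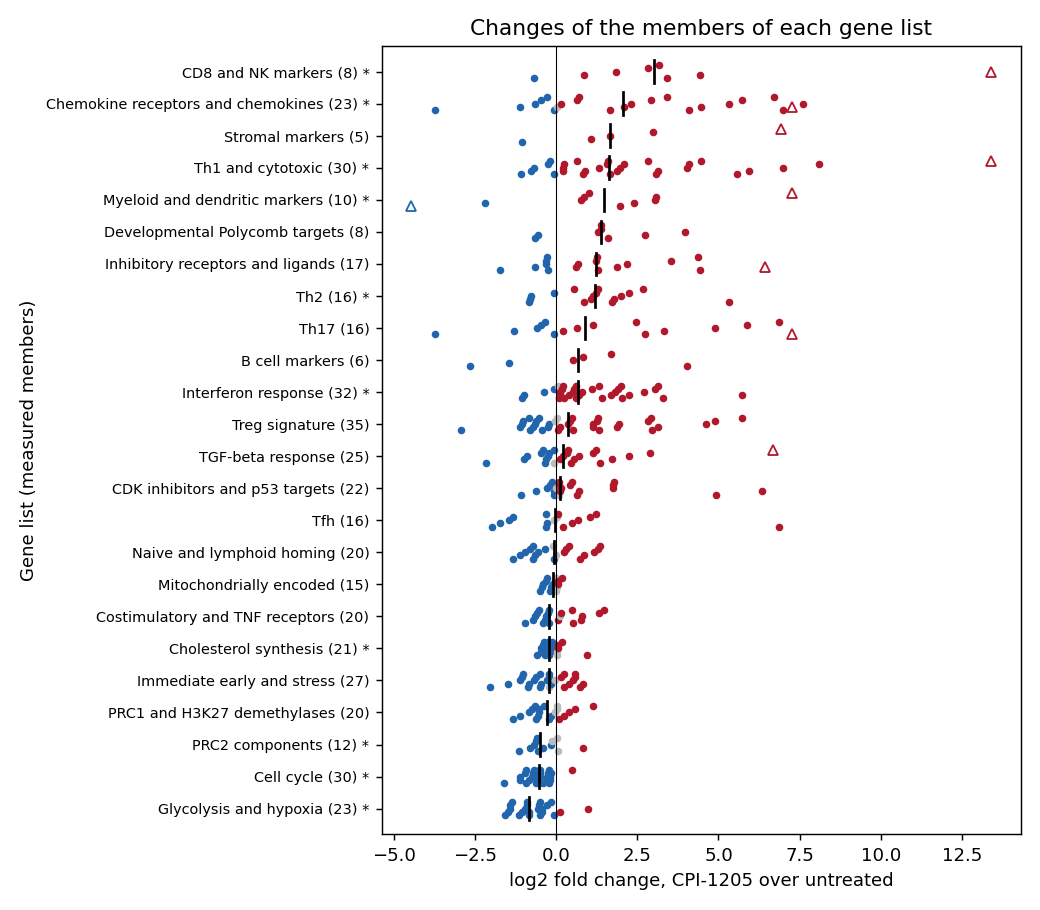
Log2 fold changes of the measured members of the 24 lists with at least 5 of them, ordered by the median (black line). Red and blue points passed the threshold, grey points did not, open triangles are genes with 3 or fewer counts in a group, and an asterisk marks the 10 lists called by camera at the preset correlation. With an estimated correlation 3 of these calls held. Glycolysis and hypoxia has the lowest median, -0.83, and cell cycle the next, -0.52.

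Markers of other cell types were measured beside these groups. Of 8 CD8 and NK markers, 7 rose and 1 fell (camera adjusted p = 0.017, adjusted p = 0.301 with an estimated correlation, and 0.0714 with library size only), a list that shares Gzma, Xcl1, Klrk1 and Eomes with the lists above. Cd8a went from 5.83 ± 0.39 to 52.8 ± 0.84 CPM and Klrk1 rose 7.14-fold, while Cd8b1 went from 8.79 ± 0.85 to 16.1 ± 0.82 CPM, Cd4 from 375 ± 4.9 to 259 ± 4.3 CPM and the T cell receptor component Cd3e from 111 ± 1.5 to 192 ± 4.7 CPM (SD, n = 4), the 3 last being chosen after their values were seen. Of 10 myeloid and dendritic markers 8 rose and 2 fell (adjusted p = 0.0301, adjusted p = 0.183 with an estimated correlation, and 0.131 with library size only). Cst3 rose 2.01-fold and the MHC class II genes H2-Ab1 and H2-Aa 1.81-fold and 8.49-fold, while the class II chaperone Cd74 fell by 2.20 on the log2 scale. Of 6 B cell markers 4 rose and 2 fell (adjusted p = 0.366). Ighm rose 1.76-fold, Cd79b 3.23-fold and Ebf1 16.4-fold, and Igkc fell by 2.67 on the log2 scale. Of 5 stromal markers 4 rose and 1 fell (adjusted p = 0.173). Epcam rose 2.09-fold and Krt18 7.82-fold, Sparc had 0 untreated and 65 treated counts, and Pecam1 fell by 1.07 on the log2 scale. The remaining members of these lists were below the count filter. Over the libraries of a group they had at most 20 counts among myeloid (Fcer1g, treated), 7 among B cell (Ms4a1, untreated) and 36 among stromal markers (Col1a2, treated). Lyz2, S100a8 and S100a9 had 0 counts in both groups, and Cd19 and Pax5 each had 0 untreated and 1 treated. Alas2 was the 1 erythroid marker with enough counts (0.212 ± 0.17 and 0.460 ± 0.13 CPM), and its call was lost without untreated replicate D (adjusted p = 0.0659 in edgeR, log2 fold change 0.81).

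The mitochondrially encoded genes took 3.36 ± 0.047% of counts in untreated and 3.35 ± 0.056% in treated libraries (SD, n = 4, two-sided exact permutation p = 0.657). Of the 15 genes, 3 rose, 9 fell and 3 did not pass (camera adjusted p = 0.154), led by COX3 (-0.41), ATP6 (-0.50), ATP8 (-0.43) and ND3 (-0.33), of which ATP6 and ATP8 overlap. With library size only 8 rose and 5 fell, and their median of -0.09 turned to 0.09. Among sex-linked genes Xist alone had enough counts, at -0.13 with an adjusted p of 0.0164 in edgeR. That call was lost without treated replicate A (-0.11, adjusted p = 0.0561) or treated replicate C (-0.09, adjusted p = 0.131) and with upper-quartile factors, and the value was 0.05 with library size only. The ribosomal RNA precursor Rn45s, a sign of how completely poly(A) selection removed ribosomal RNA, took 0.434 ± 0.27% of counts in untreated and 1.78 ± 1.1% in treated libraries (two-sided exact permutation p = 0.0571, n = 4). The 10 genes with the most counts took 10.7 ± 0.051% and 9.92 ± 1.0% (exact permutation p = 0.314), and the number of genes with a count was 15140 ± 337 in untreated and 16000 ± 303 in treated libraries (exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give), without adjustment for depth. Leaving out treated replicates B and D, which had the largest shares, left 9712 genes past the threshold, 1621 of them raised and 636 lowered at 2-fold.

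Without regard to size, 10155 genes (80.9% of those tested) passed the threshold of edgeR's quasi-likelihood test, 5132 raised and 5023 lowered, and 58.3% of them changed by less than 1.5-fold. The groups did not overlap in 9301 tested genes, against 2.86% of genes by chance. With library size as the only scaling, every gene shifted upward by about 0.185 on the log2 scale, giving 6796 raised and 3431 lowered genes, so that the direction of changes smaller than this shift rests on the scaling. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical, and with a coefficient of variation of 2.7% between libraries they call very small changes.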

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

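No test in this part was chosen after the result was seen. Among the named genes and measures of the libraries such as total counts, 232 groups of 4 libraries were searched for an outlying library. Its gap to the nearest of the other 3 had to exceed the share of the group's range set by Dixon's test at the 95% level. Such a gap was found in 11, where chance alone gives about 11.6, so their number was near chance. Untreated replicate C, the smallest library, stood apart on the second principal component, which held 2.19% of the variance. It lay at -20.7, against 4.28 to 9.51 in the other untreated libraries. In untreated replicate C, Gzmd was at 0.0639 CPM (a single count, with 0 in the other 3), Pla2g4f at 26.6 CPM (27.4 to 27.5) and Il24 at 4.92 CPM (3.87 to 4). In untreated replicate B, Ly6g was at 0.0372 CPM (a single count, with 0 in the others), Serpine2 at 49.9 CPM (47.6 to 47.8) and Nr4a3 at 98.6 CPM (95.6 to 95.9). In untreated replicate A, Xist was at 24.8 CPM against 26.8 to 27.1. Among treated libraries, Tigit was at 169 CPM in replicate A (176 to 177), COX3 at 3390 CPM in replicate B (3580 in the others), and in replicate D Id2 was at 179 CPM (188 to 190) and Sqle at 88.2 CPM (92.7 to 93.5). No explanation was tested for these single values.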

How the results depend on the processing

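The fixed coefficients of variation, the thinning and the removal of both libraries rich in Rn45s were chosen after seeing the data, the other alternatives before. Over the scalings, filters, DESeq2, limma voom and a threshold of 0.01, the number of changed genes ran from 9416 to 10966. Leaving out each library in turn gave 9969 to 10133 changed, 5042 to 5143 raised and 4912 to 5010 lowered genes, and changed no list call. Thinning every library to the smallest total gave 9313 changed genes against 10155. The count depended on the size required. At 2-fold 2170 genes passed (1581 raised, 589 lowered), against a 1.2-fold change 6654 (3160 lowered), and with a coefficient of variation fixed at 0.2, 4873 (2724 raised, 2149 lowered). These follow from the stricter criterion itself. At that value 16 of 23 glycolysis genes and 20 of 30 cell cycle genes still fell, and 1 of 21 cholesterol genes did.

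No pairing of the libraries by the letters A to D was seen: same-letter deviations correlated at -0.0026 to 0.034, and 2 of 8 libraries correlated best with their own letter. The spread within groups was close to counting error, so a pairing could also have gone unseen. With the letter as a replicate block 10128 genes passed, 5119 raised and 5009 lowered.

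With an estimated correlation 7 of 10 list calls of limma's camera were lost, with adjusted p of 0.124 for PRC2 components (0.00603 to 0.124 over all camera settings), 0.0631 for Th1 and cytotoxic (6.89e-07 to 0.0631), 0.23 for Th2 (0.0188 to 0.23), 0.0703 for chemokines (0.00395 to 0.0703), 0.124 for cholesterol synthesis (0.00624 to 0.179), 0.183 for myeloid (0.0107 to 0.183) and 0.301 for CD8 and NK markers (0.00603 to 0.301). For PRC2 components, chemokines and cholesterol synthesis the estimated correlation was below the preset 0.01 (-0.00071, -0.0015 and -0.04). A stronger correlation between their members therefore does not account for those lost calls. Library size alone ended the calls of Th2 (0.12), cholesterol synthesis (0.179), myeloid (0.131) and CD8 and NK markers (0.0714). Without a filter, PRC1 (0.0254, range 0.0254 to 0.252), developmental Polycomb targets (0.0414 to 0.453), inhibitory receptors (0.0497 to 0.301) and immediate early genes (0.027 to 0.252) were also called. The cause was not tested. Fry, which asks only whether a list moves one way and does not compare it with other genes, also passed PRC1 (3.3e-07), developmental Polycomb targets (9.18e-06), Treg signature (7.91e-10), Th17 (3.01e-07), Tfh (2.05e-05), naive (0.00051), inhibitory receptors (1.47e-08), CDK inhibitors (1.27e-07), TGF-beta (3.33e-07), immediate early (3.42e-08), B cell (1.99e-07), stromal (5.82e-07) and mitochondrial genes (1.75e-05). With library size only, Eed went to 0.0242 and Xist to 0.0520 on the log2 scale, which follows from the upward shift of all genes. At these depths and with 4 libraries in each group, the simulated recovery was 32% at 1.1-fold. Far fewer genes were changed in that simulation than passed in the data.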

Other observations

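The 4 gene lists of the next 2 paragraphs, the comparison of variances with counting error, the tests on NK markers and Cd8b1, and the comparison of expression bins with untreated expression were chosen only after the result was seen. Genes of amino acid synthesis, transport and tRNA charging, many of them targets of the stress transcription factor ATF4, were lower in treated cells. Of 28 measured, 27 fell, 0 rose and 1 (Wars) did not pass (adjusted p = 0.193 in edgeR), with a median log2 fold change of -1.04. Limma's camera over the 4 lists gave an adjusted p of 1.77e-11, and 0.00414 with an estimated correlation. Asparagine synthetase (Asns) went from 176 to 42.1 mean CPM, the serine synthesis enzymes Phgdh and Psat1 from 500 to 207 and from 351 to 149, Atf5 from 158 to 23.3 and Stc2 from 56.7 to 7.11. Leaving out the 5 members whose values had been seen before the list was written, 22 of 23 fell (camera adjusted p = 6.79e-10). Ribosomal protein genes fell too, 77 of 81 with a median of -0.62, 1 rising and 3 not passing, and 75 of 81 fell with library size only. That list gave an adjusted p of 2.39e-18, but 0.143 with an estimated correlation. Ribosomal protein genes have near-identical copies, so their counts are uncertain. Rpl39 and Rpl39l, which did not pass, were below 1 CPM in both groups.

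Hypoxia-inducible genes outside the glycolysis list divided. Of 22, 14 fell, 7 rose and 1 did not pass (camera adjusted p = 0.0181, and adjusted p = 0.0543 with an estimated correlation). Ak4 (-2.58), Ankrd37 (-2.50) and Pfkfb3 (-2.11) fell, and Plod1 (1.29) and Adm (1.01) rose. Without the 2 members seen beforehand the adjusted p was 0.0945. Of 13 killer cell receptor, adaptor and granzyme genes, 10 rose, 2 fell and 1 did not pass (camera adjusted p = 0.000889, and adjusted p = 0.0227 with an estimated correlation). Crtam rose from 9.80 to 84.5 mean CPM. Among the 6 members not seen beforehand, 3 rose and 2 fell (adjusted p = 0.457), so the call rests on the genes that prompted the list. In all, 44 genes had at most 3 counts over the untreated libraries and at least 100 over the treated ones, and 1 gene, Steap4, did the reverse (195 and 1 counts).

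Chance assignment of libraries was examined for the counts of changed, raised and lowered genes. Of the 35 splits of the 8 libraries into 4 and 4, 1 (the real one) gave 10155 changed, 5132 raised and 5023 lowered genes, and the highest count of any other split was 0 in each case. Every other split puts libraries of both well-separated groups on each side, so few calls were bound to follow. The splits therefore show that the groups differ, but not why. Over genes with 100 to 500 counts, the median ratio of the variance within groups to the Poisson variance was 0.946, against a median of 0.789 that counting error alone gives with 4 libraries, so variation between libraries was small but above counting error. This small spread may account for how many genes passed, and 4873 passed with a coefficient of variation fixed at 0.2. The scaling factors were excluded as the cause, since 10227 genes passed with library size only. A difference between a single treated and a single untreated culture other than the inhibitor stays open, because the labels do not say how many cultures there were, and so does an effect of the inhibitor.

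The rise of Th1 and cytotoxic genes could come from other killer cells in the treated sort, although naive CD4 T cells were sorted at the start and GFP-positive cells at the end. Of 7 NK markers, 0 both reached 1 CPM and rose. The NK receptor Ncr1 and Klra1 had 0 counts in all libraries. Klra7 had 0 untreated and 4 treated counts, Klrb1c had 15 and 30, and Eomes fell from 30.4 to 18.8 mean CPM. However, Klre1 and Fcgr3 rose below 1 CPM. NK-associated genes outside these 7 rose to 1 CPM or more, namely Klra5 (0 to 212 counts), Sh2d1b1 (0 to 161), Cd244 (2 to 251), Klrk1 (250 to 2126) and Klrd1 (694 to 3191). Klrk1 and Klrd1 belong to the Th1 and cytotoxic list itself, and the other genes were chosen after their rise had been seen. Their rise is therefore no separate sign of NK cells. Of the adaptor genes of NK receptors on the myeloid list, Tyrobp had 0 untreated and 5 treated counts and Fcer1g 1 and 20. With Ncr1 at 0 counts, these low counts argue against many NK cells. Klre1 and Fcgr3 rose, so a small share of NK cells stays open. For Cd8a itself, the gain of Cd8b1 was 0.156 of the gain of Cd8a (SD 0.023 over pairs of libraries). This argues against CD8 T cells with both CD8 chains as the whole cause, if such cells hold both transcripts in more equal amounts. No library here gives that ratio. For the cytotoxic list as a whole, a small share of CD8 T cells cannot be told apart from expression in the iTregs, because Cd8b1 gained 7.33 CPM (SD 1.2) beside a gain of 570 CPM for Prf1 and no library of CD8 T cells gives the level to compare with. An effect of EZH2 inhibition on the iTregs themselves also stays open.

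Raised genes outnumbered lowered genes 2.68 to 1 at 2-fold. The size of this imbalance depended on the scaling, with ratios of 2.76 with DESeq2-type factors, 3.18 with upper-quartile factors and 5.09 with library size only. These scalings all shifted log2 fold changes upward from the main one, by medians of 0.006, 0.048 and 0.185. An upward shift raises the ratio, so they could not test whether scaling accounts for its direction. The ratio was 2.72 with every library thinned to the smallest total, so unequal depth does not account for its direction. A hypothesis stated before its test was that loss of EZH2 activity releases weakly transcribed genes. The raised share of genes changed 2-fold was 78.4%, 73.4%, 62.8% and 55.3% from the lowest to the highest of 4 equal bins of mean expression, a difference of 23.1 percentage points, which may reflect such release. The bins were of the mean over all 8 libraries. Of 1146 raised genes in the lowest of 4 bins of untreated expression, 929 lay in the lowest bin of mean expression. These were all the raised genes of that bin, but other weakly transcribed genes lay in higher bins. Other causes of the gradient were not tested.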
